A study of Mus musculus with 8 samples.

How the data were processed

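Poly(A) RNA was sequenced from naive CD4 T cells sorted from spleen and lymph node of mice that carry floxed Satb1 alleles and a tamoxifen-inducible Cre recombinase driven by CD4 sequences. Per the labels' protocols, libraries were made with an unstranded TruSeq kit and sequenced as single reads. Per the submitters' processing notes, the tools included CASAVA 1.8.2, FastQC, R 3.5.3 and DESeq2 1.22.2, and the genome build was mm10. The aligner, the read counter and the annotation release are not given in the sources used here, nor is it stated whether reads were counted by strand.

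Tables of 2 kinds were deposited. The deposited count table holds whole-number read counts for 53465 Ensembl gene IDs, of which 23678 had at least 1 read. The deposited normalized signal table holds 16418 genes, exactly those with at least 10 reads over the 8 samples, and each of its values is the count divided by 1 size factor per sample. Gene symbols, types and positions came from the GENCODE release M21 annotation of the mouse genome (GRCm38, the assembly behind mm10), which held 53360 of the IDs (99.8%) when version suffixes were ignored.

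Samples were grouped by their labels into 4 tamoxifen-treated samples (KO) and 4 untreated samples (WT). Sample numbers were not shared between the groups, so nothing paired them. All pairs of samples within a group differed beyond sampling noise, with a chi-square per gene between 2.67 and 11.26, and each was counted as its own replicate. The labels do not say whether the samples came from separate animals, so p-values measure the spread between these samples, which can be technical.

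Counts were tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F test on KO against WT, with TMM normalization and the filterByExpr filter, which kept 11772 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are KO relative to WT, standard errors (SE) are the absolute log2 fold change over the square root of F, and levels are TMM-scaled read counts in CPM as mean ± SD. For genes with too few reads to be tested, reads were pooled per group, with exact conditional 95% intervals for the ratio and exact permutation tests on CPM. Intervals and floors cover counting error only. The floor is the level of 3 reads in the pooled reads of a group.

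In total 33 gene lists were fixed before the data were examined, of which 29 had at least 5 tested members. These were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the lists. None of the lists was chosen on these samples.

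The rule for naming genes was also fixed before the data were examined. It takes Satb1, a fixed panel of T cell genes, and the 10 largest increases and 10 largest decreases among changed genes with a mean of at least 5 CPM and no overlap between the groups, leaving out clone-like symbols and receptor segments. It adds up to 4 members of lowest adjusted p in each list with at least 3 changed members, and members needed to say how a list moved. Some genes that the rule takes are not reported here. The 3 genes inside Satb1, and Gm6934, which overlaps it, were named after their values were seen.

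The steps were tested on simulated counts for the 11772 genes of the KO against WT comparison. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery at lower levels was not tested. Among them the test recovered 89% of genes changed 1.5-fold, 98% of those changed 2-fold, 100% at 4-fold and 99% at 8-fold. Of the calls, 7.7% were unchanged genes. Camera called 0 of 58 unshifted lists. The simulated genes varied independently of each other. This result therefore does not cover lists whose members vary together, such as the type I interferon list (estimated correlation 0.491).

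Alternatives were DESeq2 1.42.0, limma-voom with sample weights, RLE size factors, library size without TMM, no count filter, a filter of 1 CPM in 4 samples, limma-trend on log2 of the deposited normalized values plus 1, a non-robust fit, and leaving out each sample in turn. For the lists, camera with an estimated correlation and the rotation test fry were added. After the data were seen, thinning of every library to 5227758 reads and leaving out Sample_2911_WT and Sample_2914_WT together were added.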

Results

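RNA-seq measured gene expression in naive CD4 T cells, sorted as CD3+CD4+CD25- cells with low or no CD44, from mice in which Satb1 can be deleted by tamoxifen. Satb1 encodes a chromatin-organising DNA-binding protein abundant in the T cell lineage. Of the 8 samples, 4 came from tamoxifen-treated mice (Sample_2907_KO, Sample_2908_KO, Sample_2909_KO and Sample_2910_KO) and 4 from untreated mice of the same genotype (Sample_2911_WT, Sample_2913_WT, Sample_2914_WT and Sample_2915_WT). KO libraries held 7544075 to 9253620 counted reads (mean 8.56 ± 0.81 M reads, SD, n = 4). WT libraries held 5227758 to 21998174 (mean 11.08 ± 7.83 M reads, SD, n = 4). The single comparison asks how naive CD4 T cells differ when Satb1 is targeted, in a study of Satb1, IL-2 and the development of Th17 cells. Tamoxifen was given to the KO samples alone, so treatment and the intended deletion coincide. KO here names the group, and does not state that Satb1 was lost.

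The targeted gene was examined first, in every sample. Satb1 (ENSMUSG00000023927.15, mm10 chromosome 17, 51736187 to 51833290, minus strand) stood at 909.9 ± 87.2 CPM in KO and 1033 ± 41.4 CPM in WT (SD, n = 4 each). The KO libraries had 855.1, 1032, 839.6 and 913.2 CPM, and the WT libraries 987.2, 1015, 1046 and 1083 CPM. The log2 fold change of -0.18 (SE 0.059) did not pass the threshold (edgeR quasi-likelihood test, adjusted p = 0.0582). An exact 2-sided permutation test over the 70 relabellings gave p = 0.0857, where 0.0286 is the smallest the design allows. Without Sample_2908_KO the log2 fold change was -0.25 and passed (edgeR adjusted p = 0.00152).

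Within Satb1, 3 unconfirmed genes annotated on the same strand fell far more than the gene that contains them. E430014B02Rik (51745529 to 51748684) fell by 3.33 on the log2 scale (edgeR adjusted p = 1.32e-07). C230085N15Rik (51757295 to 51761621) fell by 2.80 (adjusted p = 1.4e-08), and Gm36931 (51766643 to 51771443) by 3.30 (adjusted p = 2.86e-10). E430014B02Rik and C230085N15Rik lie wholly in Satb1 introns, while Gm36931 covers a Satb1 exon with 156 coding bases (51767892 to 51768047). Pooled over these 3 genes, which were singled out after their values were seen, KO held 113 reads and WT 1371, a KO level of 10.7% of WT (95% interval of the ratio 0.087 to 0.129). Satb1 itself, pooled in the same way, had a ratio of 0.858 (0.846 to 0.871). Because these genes overlap Satb1, their reads and its reads depend on how the counter assigned them. Gm6934, an unconfirmed gene that overlaps Satb1 on the opposite strand, had a log2 fold change of -0.01 (edgeR adjusted p = 0.986).

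**Figure D1:**
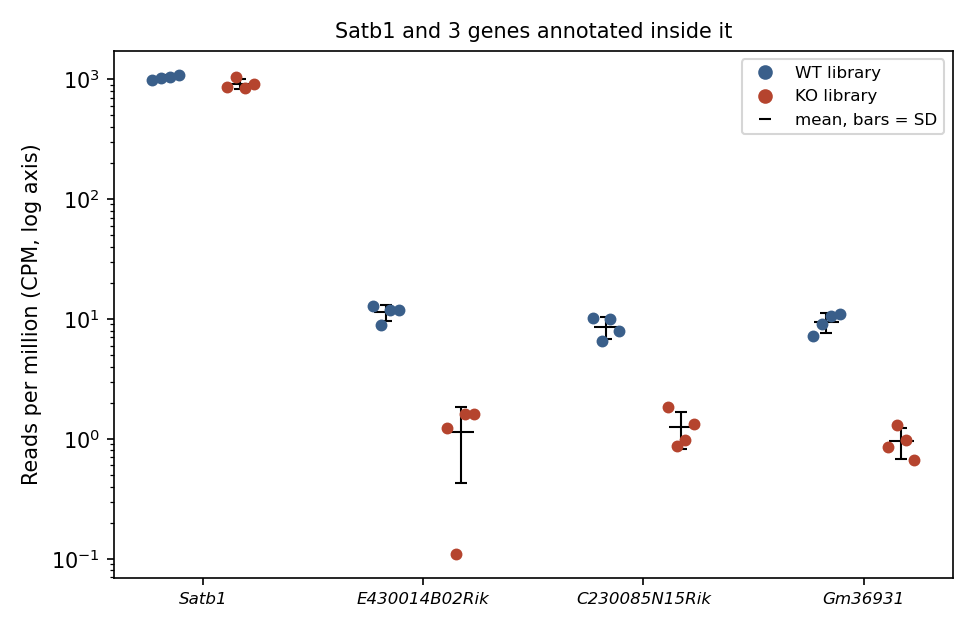
CPM on a log axis for Satb1 and the 3 genes annotated inside it, with 1 point per library, the group mean as a horizontal mark and SD as bars. The KO libraries lie below every WT library for the 3 genes inside Satb1, while Sample_2908_KO at 1032 CPM lies within the WT range for Satb1.

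Foxp3, the lineage factor of regulatory T cells, rose most among the genes named by rank. It stood at 93.4 ± 27.2 CPM in KO and 8.41 ± 1.20 CPM in WT (SD, n = 4 each), a 10.9-fold rise (log2 fold change 3.45, SE 0.298, edgeR adjusted p = 0.000881). Il10ra, a chain of the IL-10 receptor, rose 4.42-fold (121.4 ± 4.96 against 27.7 ± 1.99 CPM, adjusted p = 7.23e-19). Among changed genes with a mean of at least 5 CPM and no overlap between the groups, clone-like symbols and receptor segments left out, the largest falls were in Adamts14, an extracellular protease (log2 fold change -1.68), Dntt, the terminal transferase of antigen receptor rearrangement (-1.55), and Crtam, a surface receptor of activated T cells (-1.34). In all, 752 of 11772 tested genes changed (6.4%), 468 higher and 284 lower in KO. Most changes were small: 70.1% of the changed genes moved by less than 1.5-fold, and 104 changed at least 2-fold, 65 up and 39 down. In 658 of the changed genes the KO and WT libraries did not overlap. Among all tested genes 11.1% had no overlap, where chance gives 2.9%. Leaving out Sample_2911_WT and Sample_2914_WT together gave 481 changed genes, 323 higher and 158 lower.

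The other large increases were in Coro2a, an actin-binding protein (3.91-fold), Rsad2 (3.81-fold), Mx1 (3.75-fold), Ifit3b and Arhgap21 (both 3.49-fold), Anxa2 (3.28-fold), Unc93b1, a chaperone of endosomal Toll-like receptors (3.28-fold), and Mx2 (3.25-fold). The other large decreases, on the log2 scale, were in Gtf2ird1 (-1.24), Slc16a5, a monocarboxylate transporter family member (-1.13), Card9 (-1.04), Igsf23 (-1.03), Gen1 (-1.03), Ampd1 (-0.93) and Tex9 (-0.91). All 20 ranked genes, by the rule that chose them, separated KO from WT in every library. Slc16a5 and Tex9 overlap changed genes on the opposite strand (Gm11695, log2 fold change -1.01, and Mns1, -1.02), so their reads may not be separable. Ifit3b, Mx1 and Mx2 have close relatives that could share reads. Rsad2 missed the threshold when Sample_2911_WT, Sample_2914_WT or Sample_2915_WT was left out, with adjusted p between 0.0537 and 0.0609.

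**Figure D2:**
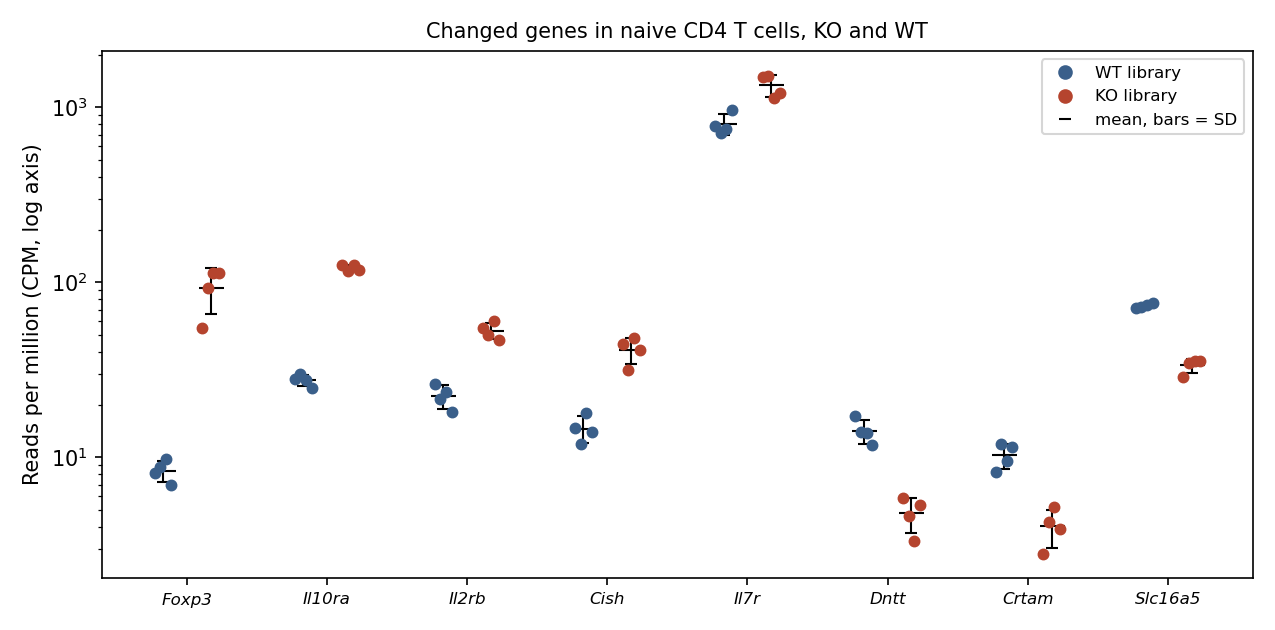
CPM on a log axis for 8 changed genes in the KO and WT libraries, with 1 point per library, the group mean as a horizontal mark and SD as bars. All 4 KO libraries lie above all WT libraries for Foxp3, Il10ra, Il2rb, Cish and Il7r, and below them for Dntt, Crtam and Slc16a5.

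IL-2 itself was near the limit of detection. Il2 had 10 reads over the KO libraries (4, 3, 2 and 1) and 2 over the WT libraries (1, 0, 0 and 1), a pooled ratio of 6.47 with a counting interval of 1.38 to 60.7, and an exact permutation p of 0.0571. The list of IL-2 and common gamma chain cytokine signalling genes rose, with 6 of 22 tested members higher and 0 lower (7 higher adjusted over the list alone; camera adjusted p = 4.72e-05, median log2 fold change 0.12). With an estimated correlation the list had an adjusted p of 0.150. Its changed members included Cish, a feedback inhibitor induced by STAT5 (log2 fold change 1.45, SE 0.133, adjusted p = 4.25e-08), and Il2rb, the IL-2 receptor beta chain (1.26, SE 0.107, adjusted p = 8.38e-10; 53.1 ± 5.83 against 22.4 ± 3.53 CPM). Il7r, the IL-7 receptor alpha chain (0.74, adjusted p = 0.0245), and the survival gene Bcl2 (0.44, adjusted p = 1.08e-05) also rose. Il2ra, which encodes CD25, had a log2 fold change of 0.41 (adjusted p = 0.392). Il7r lost its call when Sample_2907_KO, Sample_2908_KO, Sample_2911_WT or Sample_2914_WT was left out, at log2 fold changes of 0.67 to 0.72.

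The Th17 list was not called (camera adjusted p = 0.130; 2 of 15 tested members higher and 1 lower, and 7 higher and 2 lower adjusted over the list alone). Irf4, a transcription factor needed by several helper fates, rose (log2 fold change 0.91, adjusted p = 0.000647), Stat3 rose slightly (0.19, adjusted p = 0.038), and the TGF-beta mediator Smad3 fell (-0.25, adjusted p = 0.0349). Both calls were fragile. Stat3 lost its call in 9 of 18 alternatives, with library size only (adjusted p = 0.0508), a non-robust fit (0.0745), thinning (0.0514), without Sample_2911_WT and Sample_2914_WT together (0.401), and without Sample_2907_KO, Sample_2910_KO, Sample_2911_WT, Sample_2913_WT or Sample_2914_WT (up to 0.195). Smad3 lost its call in 10 of 18, with DESeq2 (adjusted p = 0.056), limma-voom (0.063), a non-robust fit (0.0515), without the same WT pair (0.336), and without Sample_2908_KO, Sample_2909_KO, Sample_2910_KO, Sample_2911_WT, Sample_2913_WT or Sample_2914_WT (up to 0.134). Rora, a Th17 factor, was at 14.6 ± 4.32 CPM in KO and 14.5 ± 2.37 CPM in WT. Il17a, Il22, Ifng and Il13 had 0 reads, which allows up to 0.0876 CPM in pooled KO and 0.0677 CPM in pooled WT. Il17f had 12 reads in KO and 14 in WT.

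Among other helper lists, Th2 genes rose (3 of 9 tested members higher, 5 adjusted over the list alone; camera adjusted p = 0.00183), with an adjusted p of 0.171 with an estimated correlation. The Th2 call was lost with no count filter (camera adjusted p = 0.124) and with limma-trend (0.05). The members were Gata3, the Th2 lineage factor (log2 fold change 0.35, adjusted p = 0.00268), Il4ra (0.27, adjusted p = 0.00846) and Stat6 (0.21, adjusted p = 0.0152). Stat6 overlaps Nab2 on the opposite strand and lost its call without Sample_2907_KO, Sample_2913_WT or Sample_2915_WT, with adjusted p between 0.059 and 0.0779. Il4 had 6 reads in KO and 8 in WT. The Th1 list was called up (camera adjusted p = 0.022, 0.150 with an estimated correlation). Of its 11 tested members 2 were higher, both also adjusted over the list alone. They were the interferon gamma receptor gene Ifngr1 (log2 fold change 1.46, edgeR adjusted p = 2.03e-11) and Runx3 (0.41, adjusted p = 0.00231). The Th1 call was lost with no count filter (median log2 fold change 0.11, camera adjusted p = 0.246), with limma-trend (0.09, adjusted p = 0.27), and without Sample_2908_KO, Sample_2910_KO or Sample_2915_WT (camera adjusted p between 0.0522 and 0.0637). Tbx21, which encodes T-bet, had 10 reads in KO and 14 in WT. The follicular helper list was not called (2 of 15 tested members higher and 1 lower, 4 and 4 adjusted over the list alone; camera adjusted p = 0.929). In it Pdcd1, which encodes PD-1, rose 2.33-fold (adjusted p = 0.000318) and Slamf6 rose (log2 fold change 0.58, adjusted p = 5.59e-07), while Bcl6 had -0.22 (adjusted p = 0.372).

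The regulatory T cell list was called up (camera adjusted p = 0.022, 0.150 with an estimated correlation), with 3 of 16 tested members higher and 0 lower (4 higher and 1 lower adjusted over the list alone). Besides Foxp3, Izumo1r (log2 fold change 0.35, adjusted p = 0.00108) and Tnfrsf18, which encodes GITR (0.50, adjusted p = 0.00851), rose. The list was not tested without Foxp3, so its call may rest in part on that gene. The median log2 fold change of the other 15 tested members was 0.09. Ctla4, an inhibitory receptor of regulatory T cells, was at 8.99 ± 1.86 CPM in KO and 7.90 ± 3.33 CPM in WT (adjusted p = 0.847). The call of this list was lost with no count filter (median log2 fold change 0.04, camera adjusted p = 0.32), with limma-trend (0.09, adjusted p = 0.213), with thinning (adjusted p = 0.0572) and without Sample_2915_WT (0.0539), and that of Tnfrsf18 without Sample_2909_KO (edgeR adjusted p = 0.0696).

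Genes of the type I interferon response rose together. Of 40 tested members 31 were higher and 0 lower (37 higher adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 5.62e-31). With an estimated correlation the list had an adjusted p of 0.150. Ifi27l2a (0.96, adjusted p = 1.02e-10), Slfn5 (1.12, adjusted p = 2.29e-09), Rtp4 (0.93, adjusted p = 4.35e-07) and Oasl2 (1.39, adjusted p = 6.61e-07) had the lowest adjusted p in the list, and the ranked genes Rsad2, Mx1, Mx2 and Ifit3b belong to it. The mean log2 CPM of the list lay between 6.06 and 6.45 in the KO libraries and between 5.22 and 5.56 in the WT libraries. For myeloid and dendritic cell markers the same mean was 3.23 to 3.41 in KO, and 3.58, 2.13, 2.48 and 3.18 in Sample_2911_WT, Sample_2913_WT, Sample_2914_WT and Sample_2915_WT. That marker list was not called (camera adjusted p = 0.154), although it passed with limma-voom (adjusted p = 0.046) and without Sample_2911_WT (0.0325).

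Cholesterol synthesis and SREBP target genes rose, with 10 of 30 tested members higher and 0 lower (14 higher adjusted over the list alone; median log2 fold change 0.25, camera adjusted p = 5.32e-08, 0.171 with an estimated correlation). Scd2, a fatty acid desaturase (log2 fold change 0.51, adjusted p = 9.02e-06), and Cyp51, an enzyme of sterol synthesis (0.57, adjusted p = 0.000129), were among the members that rose. Mitochondrially encoded genes fell, with 3 of 11 tested members lower (7 adjusted over the list alone; camera adjusted p = 0.00705, 0.488 with an estimated correlation, and fry adjusted p = 0.127). These were mt-Nd5 (-0.34), mt-Nd1 (-0.28) and mt-Cytb (-0.24). Nuclear genes of oxidative phosphorylation had 0 of 84 members past the edgeR threshold, 4 at an unadjusted p under 0.05 and 0 with DESeq2 (camera adjusted p = 0.938).

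Genes of activation and of the naive state moved in both directions. The activation and memory list was called up (5 of 26 tested members higher and 1 lower, 6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0207, 0.150 with an estimated correlation). Id2 (log2 fold change 0.80, adjusted p = 1.4e-08), the early activation marker gene Cd69 (0.73, adjusted p = 1.65e-08), Irf4 and Ly6a (0.80, adjusted p = 0.00449) rose, whereas Cd44, which encodes a marker used in the sort, fell (-0.34, adjusted p = 0.0262). Of 22 naive and quiescence genes 3 rose and 3 fell, as they did adjusted over the list alone, and the list was not called (camera adjusted p = 0.688). Slfn2 rose (0.24, adjusted p = 0.00429), while Tcf7 (-0.29, adjusted p = 0.000291), Bach2 (-0.23, adjusted p = 0.0107) and Ccr7 (-0.19, adjusted p = 0.0221) fell. Cd44 lost its call without Sample_2909_KO, Sample_2910_KO, Sample_2914_WT or Sample_2915_WT, with adjusted p up to 0.122, and with thinning (0.158). Ccr7 lost its call without Sample_2907_KO, Sample_2913_WT or Sample_2915_WT (adjusted p up to 0.104), and Bach2 without Sample_2915_WT (0.0659).

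The immediate early and handling stress list was called up (camera adjusted p = 0.0109, 0.488 with an estimated correlation, and fry adjusted p = 0.123). Of its 33 tested members 4 were higher, with the same number adjusted over the list alone. They were Cd69, Klf6 (log2 fold change 0.65), Rgs1 (1.55) and Dusp5 (0.49). The call of this list was lost without Sample_2910_KO (camera adjusted p = 0.087) or Sample_2915_WT (0.109). The p53 and DNA damage list was called up with a single changed member, Apaf1 (0.32; 3 higher adjusted over the list alone; camera adjusted p = 0.022, 0.150 with an estimated correlation), and lost its call with DESeq2 (camera adjusted p = 0.0836) and with thinning (0.134). In the cytotoxic and CD8 list, which camera did not call (1 higher and 3 lower of 12, 1 and 4 adjusted over the list alone; camera adjusted p = 0.154, but fry adjusted p = 0.0356), Ctsw (-0.63), Crtam and Klrd1 (-0.51) fell and Runx3 rose. Cd8a had 10 reads in KO and 18 in WT. Zbtb7b, which encodes the CD4 lineage factor ThPOK, had a log2 fold change of -0.05 (adjusted p = 0.783).

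Of the remaining lists, none was called with camera at the preset correlation, although fry called heat shock and unfolded protein genes (fry adjusted p = 0.0356) and NK cell markers (0.00999). Numbers adjusted over the list alone stand in brackets after each list, higher then lower. T cell lineage and thymocyte genes (5 and 5) had 4 higher and 4 lower of 24, with Dntt and Tcf7 among those that fell and Gata3 and Id2 among those that rose. T cell receptor signalling genes (4 and 5) had 3 higher and 2 lower of 38, including Ptpn22 (0.29) and Dgka (-0.22). Heat shock and unfolded protein genes (4 and 2) had 3 higher and 1 lower of 23 (Atf4 0.27, Hspd1 0.32, Hsp90b1 0.25 and Edem1 -0.19). Chromatin genes and SATB partners (6 and 3) had 3 higher and 2 lower of 35, including Baz1a (0.31), Pml (0.32) and Tet1 (-0.32). Homing genes (1 and 2) had 1 higher and 2 lower of 20. Oestrogen receptor targets (2 and 1) had Bcl2 higher and Esr1 lower (-0.43) of 9, glycolysis genes (1 and 1) Slc2a3 higher (0.46) and Pdk1 lower (-0.66) of 27, and cell cycle genes (5 and 2) Tk1 higher (0.73) and Ccna2 lower (-1.86) of 29. The glycolysis list passed without Sample_2908_KO (camera adjusted p = 0.0451) or Sample_2911_WT (0.0325). B cell markers (0 and 1) had Ighm lower (-0.27) of 8, and NK cell markers (2 and 1) had Il2rb and Gata3 higher and Cd7 lower (-0.65) of 5. TCR variable segments (0 and 0) had Trbv16 lower (-0.30) of 75, histone genes (0 and 1) Hist2h2be lower (-0.68) of 13, and myeloid markers (2 and 0) Bst2 (0.65) and Ly6c2 (adjusted p = 0.019) higher of 10. Ribosomal protein genes (0 and 0) had Rpl7l1 higher (0.26) of 81. Their median log2 fold change of 0.01 became -0.11 without Sample_2914_WT (camera adjusted p = 1.62e-10). Erythroid, stromal and sex-linked markers had 3, 1 and 4 tested members, of which 0 passed with edgeR or DESeq2 and 1 erythroid member had an unadjusted p under 0.05 and was lower adjusted over the list alone. Immunoglobulin segments had 0 tested members.

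**Figure D3:**
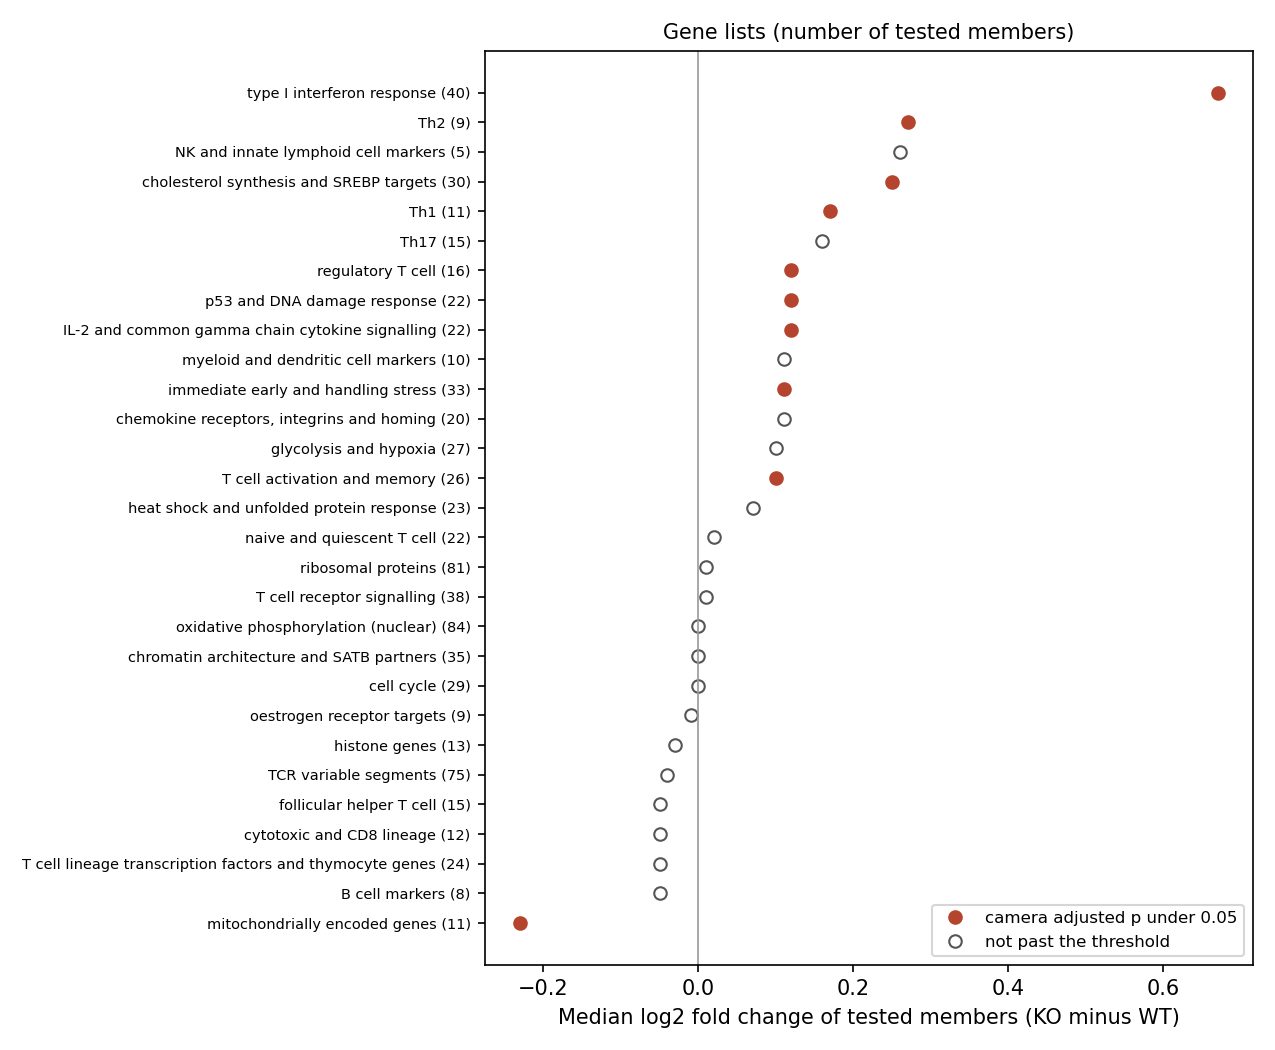
Median log2 fold change (KO minus WT) of the tested members of 29 gene lists, with the number of tested members in brackets and filled points for lists with a camera adjusted p under 0.05 at the preset correlation. The type I interferon list lies highest at 0.67 and the mitochondrially encoded genes lowest at -0.23.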

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

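The tests in this part were chosen after the result was seen, except the one on unspliced reads and those on tamoxifen, which were written before.

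Within groups of 4 libraries, 1 library stood far from the other 3 in 8 of 222 groups examined, where chance gives about 1 in 20. Arhgap21 was at 7.45 CPM in Sample_2908_KO against 10 to 10.2 in the other KO libraries, and Slc16a5 at 28.9 CPM in Sample_2907_KO against 34.6 to 35.6. Slfn5 was at 520 CPM in Sample_2908_KO against 407 to 418. Il4ra was at 416 CPM in Sample_2915_WT against 381 to 385, and Atf4 at 184 CPM in Sample_2915_WT against 179 to 180. The mean log2 CPM of the IL-2 and common gamma chain list was 7.01 in Sample_2914_WT against 7.07 in the other WT libraries. List means were rounded before this check and the other WT libraries tied, so this small difference may be flagged through rounding. The mean log2 CPM of the ribosomal protein genes was 8.33 in Sample_2914_WT against 8.93 to 8.98. That of the TCR variable segments was 0.93 in Sample_2911_WT against 2.02 to 2.20.

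The 752 changed genes were set against the other ways of splitting the samples. Of the 35 splits into 4 and 4, 1 gave as many genes, the real one. The highest of the others gave 1 gene. The real split was thus the highest of 35, the strongest result that this number of splits allows. Every other split mixes KO and WT libraries, which adds to the spread within its groups. The splits cannot separate the treatment from any other difference between KO and WT samples.

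Inside Satb1, 3 genes fell to 10.7% of WT while Satb1 stood at 85.8%. Most KO cells keeping the gene intact and transcribed as in WT is argued against by the 10.7% itself (counting interval 8.7 to 12.9), since such cells would hold these genes near the level of Satb1. These are the values that raised the question, not a separate test. They also rest on how the counter assigned reads that overlap Satb1. A general loss of unspliced reads in KO would lower unconfirmed genes inside other genes too. On the same strand inside other tested protein-coding genes lay 140 such genes. Their median log2 fold change was -0.03 (95% bootstrap interval over genes -0.15 to 0.04), which argues against a general fall of such genes. Whether they cover exons was not checked, so some of their reads may be spliced, and unspliced reads alone were not measured. Loss of the segment with these 3 genes alone cannot be told apart from a longer one, since the 2 further genes upstream in Satb1, at 27.2% of WT (13.3 to 51.3) from 12 and 57 reads, had too few reads to be tested. Less transcription of the locus, intact or not, with long-lived Satb1 RNA stays open, untested.

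Foxp3 rose 10.9-fold in cells sorted as CD25-negative, a gate that would remove most regulatory T cells. More regulatory T cells in the KO sort would raise their other markers too, provided that cells passing the CD25 and CD44 gates carry them. Whether such cells do was not tested. The 6 other regulatory T cell list members under 10 CPM in WT had a median log2 fold change of -0.03 (95% bootstrap interval over these genes -0.53 to 0.27). Il2ra was the highest of them at 0.41, but it encodes CD25, against which the cells were sorted. With limits of 20 CPM or none, the medians were 0.07 (-0.09 to 0.25) and 0.09 (0.03 to 0.36). Tnfrsf18, Izumo1r and Nt5e (0.79, edgeR adjusted p = 0.0944) lie among the 15 members without a limit. These medians lie far below the log2 rise of Foxp3, but a smaller gain of regulatory T cells is not excluded. The intervals of the medians resample genes, so they do not measure the spread between samples. Reads of the neighbours that overlap Foxp3 are argued against by their largest log2 fold change of 0.09 (SE 0.22). An effect through Satb1 and one of tamoxifen itself cannot be told apart, since 0 libraries outside the KO group had tamoxifen.

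Interferon response genes rose by a median of 0.67. A single KO library as the cause is argued against by the lowest KO library, which lay 0.50 above the highest WT library on the mean log2 CPM of the list. Reads from myeloid cells left in the CD3+CD4+ sort are argued against by the summed level of 26 myeloid and dendritic cell markers outside the interferon list, 254.6 CPM in KO and 242.2 CPM in WT. This sum rose by 12.4 CPM (95% t interval -21.4 to 46.2), where the interferon list gained 1505 CPM (848.1 to 2161.9). The comparison assumes that myeloid cells carry at least as many CPM of these markers as of interferon genes, which was not tested. Most of the sum came from the few markers above 10 CPM in WT. The 23 markers under that level summed to 29.4 CPM in KO and 28.1 CPM in WT, a rise of 1.3 CPM (-24 to 26.6). The median log2 fold change of the 9 tested markers, 0.09 (-0.32 to 0.92), was too wide to decide. Tamoxifen and an effect through Satb1 cannot be told apart here either, with 0 libraries that separate them.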

How the results depend on the processing

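Thinning and the joint removal of Sample_2911_WT and Sample_2914_WT were chosen after seeing the data. The alternatives fixed before the data were examined gave 562 to 895 changed genes, and every gene called both there and in the reported analysis kept its sign. Those fits share all or most of the libraries, so a reversed sign among such genes was unlikely from the start. Of 81 named genes, 55 kept their call and sign in all 18 alternatives and 3 reversed in at least 1. Satb1 passed the threshold with limma-voom (-0.19, adjusted p = 0.0181), library size only (-0.20, 0.0364), no count filter (-0.19, 0.0191), limma-trend (-0.19, 0.03) and thinning (-0.19, 0.0491), and ranged from -0.25 to -0.15 when single samples were left out. Over all alternatives its adjusted p ran from 0.00152 to 0.216. Genes near 0 reversed: Rora with limma-voom (-0.06), limma-trend (-0.02), thinning (-0.20) and without Sample_2911_WT and Sample_2914_WT (-0.04), and from -0.21 to 0.13 when single samples were left out; Ctla4 without both WT samples (-0.04) and from -0.07 to 0.27 with single samples left out; and Zbtb7b from -0.10 to 0.02 with single samples left out. The ribosomal protein median ranged from -0.11 to 0.06 with single samples left out, lowest without Sample_2914_WT, and was -0.12 without both WT samples. Leaving out both gave 481 changed genes and 158 lower ones, with fewer samples in the test, and 16 named genes lost their calls. No count filter and limma-trend each ended the calls of 3 lists (regulatory T cell, Th1 and Th2). Camera called 0 lists with an estimated correlation, against 10 with the preset one, 8 lists having an unadjusted p under 0.05, and fry called 11. Of these 8 were called by camera too, fry leaving out the mitochondrially encoded and immediate early lists and adding the cytotoxic, heat shock and NK lists. The causes of the differences between these settings were not tested. Single samples also decided the calls of Edem1 (also lost with a non-robust fit, 0.0623), Cd4, Hsp90b1, Dusp5 and Klrd1, with adjusted p up to 0.115. Il2, Il4, Il13, Il17a, Il17f, Il22 and Ifng had too few reads for the test. Whether depth or low expression was the reason was not tested, and Sample_2914_WT, the deepest library, had 0 reads of Il2.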

Other observations

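Genes in this part outside the fixed rule, and both tests, were chosen after their values were seen.

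Receptor genes for cytokines were prominent among the increases. Of 26 tested genes whose symbols name interleukin or interferon receptors, 6 rose (Il10ra, Ifngr1, Il2rb, Ifnar2, Il4ra and Il7r) and 1 fell, Il1rl2 (log2 fold change -0.43, adjusted p = 0.0142). Ifnar2, a chain of the type I interferon receptor, rose by 0.41 (adjusted p = 0.000291), while its partner chain Ifnar1 had 0.09 (adjusted p = 0.385). Ifngr1 was at 308 ± 19.6 CPM in KO and 113 ± 14.8 CPM in WT (SD, n = 4 each), and Ifngr2 had a log2 fold change of 0.02 (adjusted p = 0.935). Il2rg, the shared gamma chain, had 0.04 (adjusted p = 0.788).

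The hypothesis that these receptors may rise as a class was tested with camera on the 26 genes, which gave a camera p of 5.39e-06, and a camera p of 0.00225 with an estimated correlation. Without Il10ra, Ifngr1 and Il2rb, which prompted it, the other 23 gave a camera p of 0.00431, and a camera p of 0.0197 with an estimated correlation. Since the class was chosen after members of it were seen to rise, and the 23 still hold some of these, these values leave the hypothesis open, and most of the 26 did not pass the gene-level test.

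Changed genes also lay next to each other. Among neighbouring tested genes more than 10 kb apart, 39 of 6344 pairs changed in the same direction, where 10000 permutations gave 7 to 21 (p = 1e-04, the smallest they can give), and 13 pairs changed in opposite directions (p = 0.45). Permutation within 10 bins of expression gave 8 to 22 (permutation p = 1e-04). Without pairs whose symbols share their first 3 letters, as gene families do, 28 of 6082 pairs remained (permutation p = 8e-04). Examples outside such families are Pdlim4 (-0.55) with P4ha2 (-1.19), Gm4956 (1.59) with Kcnq5 (2.06), and Pdk1 (-0.66) with Rapgef4 (-0.59). These values are consistent with regional control as a hypothesis, but genes of 1 pathway that lie together, such as Rsad2 and Cmpk2, would give the same excess.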
